A study of Canis lupus familiaris with 6 samples.

How the data were processed

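Total RNA was extracted with Trizol from 6 canine primary osteosarcoma lines grown in medium with 10% serum to about 70 to 80% confluency, per the labels. Biotin-labelled cRNA was made from 10 µg of total RNA and hybridised to Affymetrix canine arrays, 1 array per line, per the labels' protocols. MAS5 is the only tool named, per the submitters' processing notes, with no version. The deposited values were on a log2 scale: raised to base 2 their maximum lies within the range of a 16-bit scanner, while a natural or base-10 log would place it beyond that range. The deposited log2 columns had nearly equal quantiles and no value below 1.97, which is unusual for MAS5 signals, so the summary method behind them is not settled here. Because the table was already on a log2 scale, no offset was added, and the values were used as deposited. No detection calls were used, and 0 columns were left out.

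Of 43035 rows, 111 were control probe sets, which entered only the control measures. Of the other 42924, 29254 had 1 gene symbol in the platform annotation, which can be old, 439 had several and 13231 were unnamed here. Symbols were updated through gene identifiers to the RefSeq table of assembly UU_Cfam_GSD_1.0 for 27680 probe sets, and 1574 kept the annotation's symbol. That table was used for names and for which genes neighbour each other. Tested were the 21462 probe sets whose mean over the 6 arrays lay at or above the median of all non-control probe sets, a log2 value of 6.07. The groups were compared with limma 3.58.1 (lmFit and eBayes, no covariate) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. For the gene level, the brightest probe set with exactly 1 symbol stood for each gene, giving 9145 genes. The replicate numbers of the lines follow accession order and pair nothing.

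The 35 gene lists were fixed before the data were examined. The 29 with at least 5 measured genes were tested with camera at its preset correlation of 0.01, adjusted over those lists, with camera at an estimated correlation and fry as alternatives; fry tests whether the genes of a list move one way on balance and does not compare the list with other genes. 0 lists passed with an estimated correlation and 5 with fry, 4 of which also passed camera at its preset correlation. Members were counted over all genes and adjusted over the list alone. The rule for named genes was fixed at the same time. It took, in each direction, the 12 genes with the largest log2 difference among passing probe sets with 1 symbol, each gene by its probe set of smallest p, then up to 4 members of each list by smallest p at the gene level, and all measured osteosarcoma genes. Values in the paragraphs on lists are those of the gene level. Control measures were compared with two-sided exact permutation tests.

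The alternatives fixed beforehand were no filter or an upper-quartile filter on dim probe sets, quantile normalization, centring on the 75th percentile, an intensity trend, array weights, robust eBayes, the mean of a gene's probe sets, leaving out each line in turn, and the GAPDH transcript-end ratio as a covariate. The 2 planned offsets did not apply to a log2 table and were not run. Centring on the hybridization controls, the mean ratio of the 4 control pairs as a covariate, and leaving out both UWKOS6 and UWKOS8 were added after the data were seen. With UWKOS6 and UWKOS8 left out, UWKOS2 was alone in its group and was assumed to vary like the tumorigenic lines.

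The fit was tested on simulated data with the means and spreads of the 21462 probe sets and 200 of them changed. It recovered 24% of the changes of 1 on the log2 scale, 78% of those of 2, 90% of those of 4 and 94% of those of 6, 50 of each size, and called 9 unchanged probe sets. The noise was drawn separately for each probe set, without effects shared across a line, so rates in the real data can differ. In a simulation of 29 lists over 9145 genes, camera called the 1 list that was moved and 0 others; the simulated genes were independent of one another, which real genes are not. A scan for neighbouring genes that were low or high in 1 line, or past the threshold, was added after the data were seen; it counted adjacent pairs among 8651 tested genes in chromosomal order and compared them with 10000 shuffled orders. On simulated calls over those 8651 genes a planted run of 6 neighbours gave a permutation p of 1e-04, the smallest the shuffles can give. Scattered calls gave a permutation p of 1, which was fixed in advance because they were evenly spaced with no neighbours. The rate of false calls of the scan was therefore not tested. Figures were drawn with matplotlib 3.10.9.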

Results

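Gene expression was measured in 6 primary cell lines grown from canine osteosarcoma, a malignant bone tumour. The lines UWKOS1, UWKOS3 and UWKOS7 formed tumours after transplantation into mice and are called tumorigenic here (n = 3). The lines UWKOS2, UWKOS6 and UWKOS8 formed none and are called non-tumorigenic (n = 3). RNA came from the cultured cells, not from the transplants, and 1 Affymetrix array was hybridised per line. The comparison addresses which transcripts differ between lines that can and lines that cannot grow as tumours in mice. Each array gave a log2 value for 43035 probe sets, with array medians between 6.03 and 6.05. The number of arrays limits the precision of every difference, and a p-value here measures the spread between these lines, since no line was arrayed more than once. All differences are tumorigenic minus non-tumorigenic on the log2 scale unless stated otherwise.

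FZD6, a Frizzled receptor for Wnt ligands, showed the largest rise in the tumorigenic lines among the tested probe sets. It averaged 11.26 ± 0.14 (SD, n = 3) there and 3.48 ± 0.33 (SD, n = 3) in the non-tumorigenic lines, a difference of 7.78 (limma adjusted p = 9.93e-05). Its other probe set differed by 4.49 in the same direction (limma adjusted p = 0.00113). CA2, a carbonic anhydrase, rose by 6.29 with an SE of 1.32, and its tumorigenic values ranged from 6.02 in UWKOS7 to 11.52 in UWKOS1. BMP7, a bone morphogenetic protein, rose on all 3 of its probe sets, by 2.97 to 5.52. SOX2, a transcription factor of pluripotent stem cells, rose by 3.34 with an SE of 0.49, and the ERBB ligand NRG1 rose by 3.55 with an SE of 0.62. A further tested probe set of NRG1 differed by 2.94 and did not pass (limma adjusted p = 0.0714). The remaining higher genes taken by the naming rule were LYSMD2 (5.69), the interleukin receptor chain IL13RA2 (4.67), the transketolase-like TKTL1 (4.35), the guanylate cyclase subunit GUCY1B1 (4.12), the RNA-binding protein IGF2BP1 (4.07), the fatty acid-binding protein FABP5 (3.98) and the fibrillin FBN2 (3.33).

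ASPN, a leucine-rich matrix proteoglycan, fell in the tumorigenic lines. It averaged 4.76 ± 0.95 (SD, n = 3) there and 11.63 ± 0.19 (SD, n = 3) in the non-tumorigenic lines, a difference of -6.87 (limma adjusted p = 0.00366). Group means under the dim-probe filter value of 6.07, as in FZD6 and ASPN, are not known to lie above background, so the size of such differences is uncertain. EFEMP2, a fibulin of elastic fibres, fell by 6.32 and by 4.73 on its 2 probe sets, and the thrombospondin THBS2 fell by 5.69 and 6.24. The growth factor FGF7 fell by 6.68, and GAS6, a ligand of the receptor AXL, fell by 5.48 and by 3.19 on its 2 tested probe sets. MTAP, an enzyme of methionine salvage, fell by 6.22 and by 4.02. FXYD1, a regulator of the sodium pump, fell by 5.90 (limma adjusted p = 0.000129). CCN3 fell by 5.60 on the probe set of smallest p, while another tested probe set differed by -2.03 and did not pass (limma adjusted p = 0.0809). FGL2 fell by 5.15, the formin FMN2 by 5.02, and HNMT, which methylates histamine, by 4.87. The largest lower difference among the named genes, -7.87 (SE 0.15, limma adjusted p = 2.00e-05), came from a probe set of EIF2S3, a subunit of a translation initiation factor. The probe sets of this gene disagreed: its other 2 were bright in both groups and differed by 0.43 and 0.68 in the opposite direction. 10 of these 24 genes stayed past the threshold when any 1 line was left out, namely FZD6, TKTL1, GUCY1B1, EIF2S3, ASPN, FGF7, EFEMP2, FXYD1, GAS6 and HNMT. The others did not pass without UWKOS6, and of them only FBN2, FMN2, LYSMD2, MTAP and THBS2 passed without UWKOS8. CA2 passed in no fit with a line left out except that without UWKOS7. With the GAPDH transcript-end ratio as a covariate 6 of the 24 passed, with the mean ratio of the control pairs 8, and without both UWKOS6 and UWKOS8 4, namely FZD6, EIF2S3, EFEMP2 and FXYD1. Of the 10 genes named above, ASPN and GUCY1B1 passed with neither covariate, and no named gene outside the 10 passed with either.

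**Figure D1:**
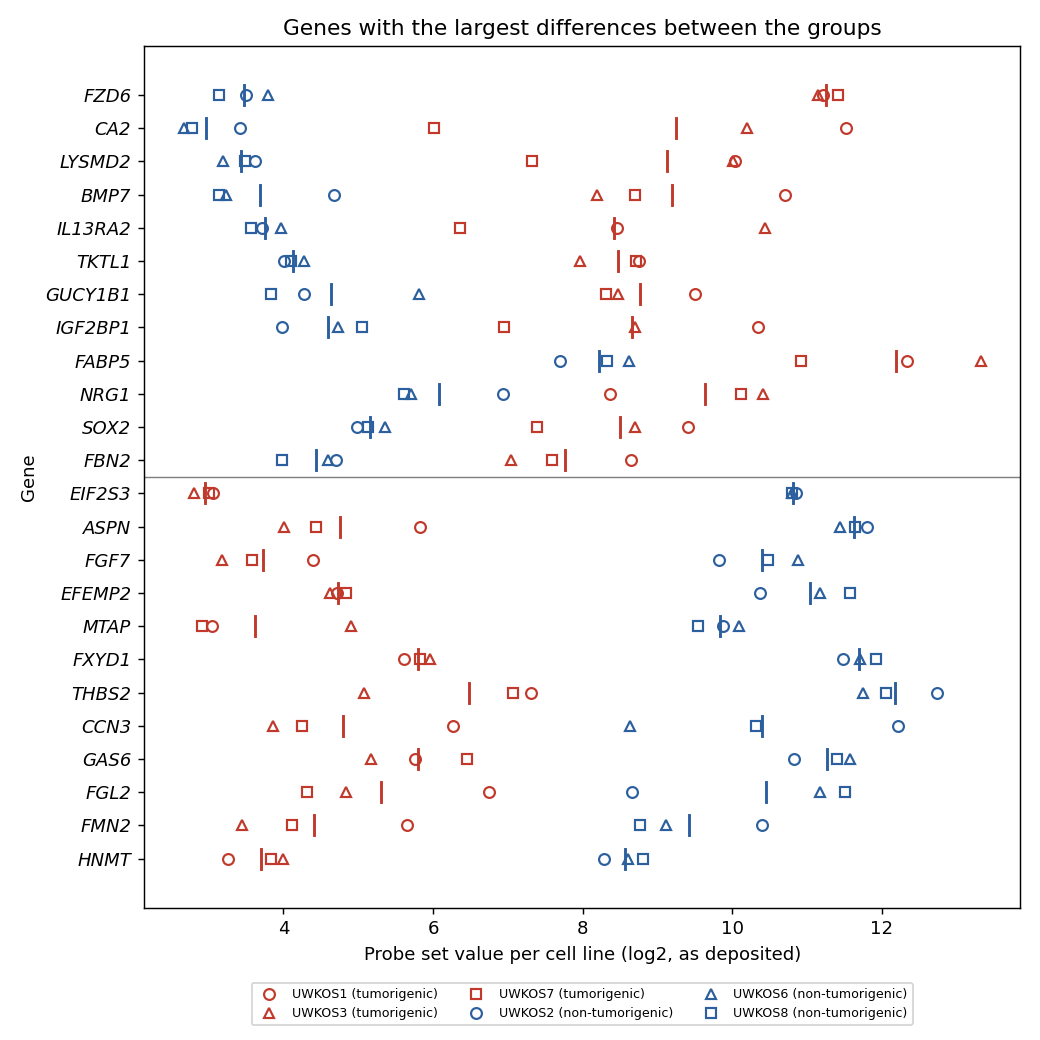
Log2 value in each of the 6 lines (points, 1 per line) and group mean (vertical bars) for the 24 genes taken by the naming rule, 12 higher in the tumorigenic lines above the grey line and 12 lower below it. The 3 tumorigenic and the 3 non-tumorigenic lines do not overlap for any of these genes; for FZD6 the means were 11.26 and 3.48.

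Genes of the cell cycle were higher in the tumorigenic lines. Of 31 measured genes of the list for G1/S and DNA replication, 16 rose, 0 fell and 15 did not pass, with a median difference of 1.32; adjusted over the list alone, 26 rose. CDCA7 rose by 1.78, the replicative helicase subunit MCM3 by 2.11, the DNA polymerase subunit POLE2 by 1.91, and GINS2 was 2.84-fold higher. Of 32 measured genes of the list for G2/M and mitosis, 11 rose, 0 fell and 21 did not pass, with a median of 1.26; adjusted over the list alone, 19 rose. BIRC5, a protein of the chromosomal passenger complex, rose by 1.45, the mitotic kinase AURKA by 2.16, the anaphase activator CDC20 by 1.72 and CDCA8 by 2.14. Both lists passed the list test (camera adjusted p = 4.48e-11 and 8.91e-09), but neither passed with an estimated correlation (adjusted p = 0.442 and 0.584), and with fry G1/S passed (adjusted p = 0.0431) and G2/M did not (adjusted p = 0.0700). At least 9 lists passed camera in 6 of the 10 splits of the lines into 3 and 3, the real one included. Camera passes alone thus do not set the real groups apart. Without UWKOS6, 0 members of either cell cycle list passed on their own, but only 12 of 9145 genes passed in all. With so few, a count of 0 does not set these lists apart from other genes. Without UWKOS8, 15 members of each list passed. The transcript-end ratios given below were higher in UWKOS6 and UWKOS8. Without both lines the list medians were 1.40 and 1.30.

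Genes of the extracellular matrix and its turnover were mostly lower in the tumorigenic lines. Among 35 measured collagens and matrix glycoproteins, 5 fell, 1 rose and 29 did not pass, with a median of -1.14 (camera adjusted p = 2.84e-05; adjusted p = 0.442 with an estimated correlation and 0.0700 with fry). Adjusted over the list alone, 10 fell and 2 rose. COL4A2, a basement membrane collagen, fell by 1.57, and THBS1 fell by 1.89; the member that rose was FBN2. Among 18 measured matrix proteases and their inhibitors, 5 fell, 1 rose and 12 did not pass, with a median of -1.07. The camera adjusted p was 0.00202, or 0.273 with an estimated correlation, and the fry adjusted p was 0.00921. Adjusted over the list alone, 8 fell and 1 rose. The aggrecanase ADAMTS5 fell by 3.26, the gelatinase MMP2 by 4.35, and the protease inhibitors TIMP2 and RECK by 1.62 and 1.18. PLAU, the urokinase, was the member that rose, by 2.02; it lay outside the naming rule and was chosen after its value was seen. Without the filter on dim probe sets the protease list did not pass (camera adjusted p = 0.136). That filter had left out the collagenase MMP1 (3.32) and the stromelysin MMP3 (2.64), both higher in every tumorigenic line than in any other. Without it MMP3 passed (limma adjusted p = 0.0267) and MMP1 did not (limma adjusted p = 0.238). Without UWKOS6, where 12 of 9145 genes passed in all, 0 members of either list passed on their own. Without both UWKOS6 and UWKOS8, the lines with the higher transcript-end ratios, the list medians were -1.05 and -0.79.

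Markers of contractile and stromal cells were lower in the tumorigenic lines as lists. Of 12 measured smooth muscle and myofibroblast markers, 3 fell, 0 rose and 9 did not pass, with a median of -1.71 (camera adjusted p = 4.60e-05; adjusted p = 0.442 with an estimated correlation and 0.0532 with fry); adjusted over the list alone, 8 fell. The smooth muscle actin ACTG2 fell by 3.19, TGFB1I1 fell by 1.21 and the tropomyosin TPM2 was 2.83-fold lower, while CSRP1 differed by -2.36 without passing (limma adjusted p = 0.0604). Of 17 measured fibroblast and mesenchymal stroma markers, 0 passed on their own, also when adjusted over the list alone. Still, 16 were lower on average, with a list median of -1.24. The camera adjusted p of the list was 0.00107, or 0.273 with an estimated correlation, and its fry adjusted p was 0.0431. The smallest p-values in that list belonged to COL6A1 (-1.51), FN1 (-1.92), FAP (-3.86) and PDPN (-2.87). Without UWKOS6, where 12 of 9145 genes passed in all, 0 smooth muscle markers passed on their own. Without both UWKOS6 and UWKOS8, which had the higher transcript-end ratios, the medians of the smooth muscle and fibroblast lists were -1.90 and -1.05.

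Adhesion genes and the list for receptor tyrosine kinases and their ligands held some lower members. Among 25 measured integrins, cadherins and other adhesion genes, 4 fell, 0 rose and 21 did not pass, with a median of -0.67 (camera adjusted p = 0.00722; adjusted p = 0.442 with an estimated correlation and 0.0824 with fry), and the same numbers held adjusted over the list alone. They were the cadherin CDH13, which was 3.99-fold lower, the fibronectin receptor chain ITGA5 (-2.62) and the tetraspanins CD63 (-0.98) and CD151 (-0.72). Among 27 measured receptor tyrosine kinases and ligands, 4 fell, 0 rose and 23 did not pass, likewise adjusted over the list alone. The camera adjusted p was 0.0174, or 0.442 with an estimated correlation, and the fry adjusted p was 0.0492. FGF7, GAS6, IGFBP6 (-2.66) and FGF2 (-2.49) fell, and none of these is a receptor. Without UWKOS6, where 12 of 9145 genes passed in all, 0 adhesion genes passed and, of the receptor and ligand list, FGF7 and GAS6 did. Without both UWKOS6 and UWKOS8, which had the higher transcript-end ratios, the list medians were -0.71 and -0.16. Those medians rest on UWKOS2 as the lone non-tumorigenic line. The median of the receptor and ligand list was -0.20 with all 6 lines, and it was 0.00206 when the arrays were centred on the hybridization controls. Without the filter on dim probe sets this list did not pass (camera adjusted p = 0.0561). Ribosomal protein genes had a median of 0.23; of 50 measured, RPL26 rose, by 1.21, 0 fell and 49 did not pass (camera adjusted p = 0.00492; adjusted p = 0.602 with an estimated correlation and 0.0526 with fry). Adjusted over the list alone 0 passed, and without UWKOS6 RPL26 did not pass. The ribosomal median was 0.43 with the arrays centred on the hybridization controls and 0.15 with them centred on the 75th percentile. The list did not pass without UWKOS8 (camera adjusted p = 0.0604), without both UWKOS6 and UWKOS8 (camera adjusted p = 0.176), or with the GAPDH or the mean transcript-end ratio as a covariate (camera adjusted p = 0.164 and 0.0786).

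**Figure D2:**
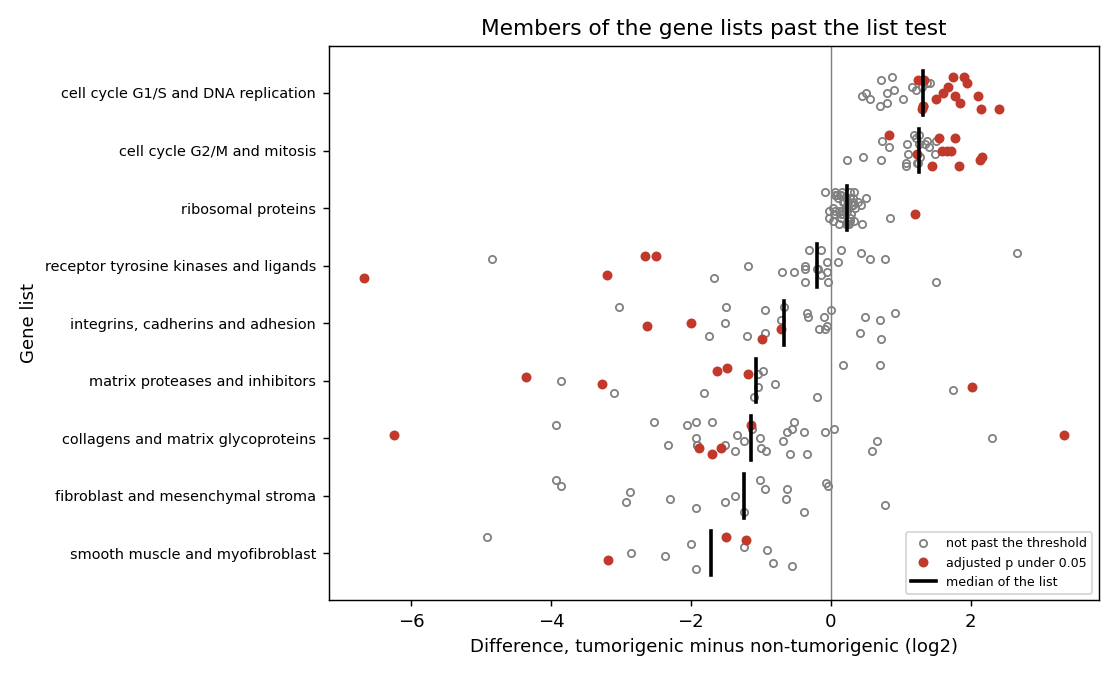
Difference between the groups (tumorigenic minus non-tumorigenic, log2) for each measured member of the 9 gene lists that passed the camera test; filled points are genes with an adjusted p under 0.05 over all genes, open points are genes that did not pass, and black bars are list medians. The cell cycle lists lie to the right of 0, with medians of 1.32 and 1.26, and the smooth muscle list to the left, with a median of -1.71.

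Among the genes fixed beforehand for their known part in osteosarcoma, FZD6, MYC and CDK4 rose. Of 14 measured, 3 rose, 0 fell and 11 did not pass, and the same numbers held adjusted over the list alone. The list did not pass camera (adjusted p = 0.488; adjusted p = 0.613 with an estimated correlation), while it passed fry, which does not compare it with other genes, in the upward direction (adjusted p = 0.00921). The median was -0.13, with 8 of the 14 members lower on average, while the mean was 0.63 and the direction of the test was upward. FZD6, at 7.78, weighs heavily on that mean, and the next largest difference was 1.32 for MYC. Neither list test was repeated without FZD6. FZD6 rose as given above, the oncogene MYC rose by 1.32 (SE 0.23) and the cyclin-dependent kinase CDK4 by 0.95 (SE 0.18). Of these only FZD6 passed without UWKOS6, where limma adjusted p was 0.0947 for MYC and 0.112 for CDK4, or without both UWKOS6 and UWKOS8; MYC also failed without UWKOS3 or UWKOS8, and CDK4 without UWKOS1, UWKOS2 or UWKOS3. The differences of the members that did not pass were -0.79 for CCND1, 0.74 for JUN, -0.29 for S100A6, -0.31 for IGF1R, -0.26 for EZR, 0.22 for RUNX2, 0.43 for MET, -0.37 for VEGFA, -0.18 for ERBB2, -0.33 for FOS and -0.08 for SETD2. The interval for FOS ran from -2.39 to 1.72, so a change of that size in either direction was not excluded. A further 4 members lay below the filter on dim probe sets and did not pass without it. RB1 differed by -1.48 (limma adjusted p = 0.069 without the filter), FAS by -0.65, ALPL by -0.24 and DLG2 by -0.19.

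Of the 29 lists tested 20 did not pass, the osteosarcoma list among them, with camera adjusted p between 0.0628 and 0.77. Of these 20, 8 passed camera in at least 1 alternative. The hypoxia list passed, downward, with the GAPDH transcript-end ratio as a covariate (camera adjusted p = 0.037) and without both UWKOS6 and UWKOS8 (camera adjusted p = 0.0486), and the osteoblast list, also downward, without both lines (camera adjusted p = 0.0486); the osteoblast list passed in 7 alternatives in all. Of the genes in these lists, and in those too short to test, only FZD6 passed on its own without UWKOS6. In that fit 12 of 9145 genes passed in all. In the Wnt list, of 21 measured, FZD6 rose while APC, a brake on Wnt signalling, fell by 1.03 and the co-receptor LRP5 by 1.16; the median was -0.16 and the mean 0.09, with a downward test. Among 7 measured Wnt antagonists and feedback targets, DKK3 fell by 2.51. In the list for TGF-beta and BMP, of 25 measured, BMP7 rose and LTBP2 fell by 2.06. The chemokine CXCL8 rose by 3.48 and CCL5 fell by 2.84 among 13 inflammatory genes, whose median was -0.11 and mean 0.11. Among 20 immediate early genes, MYC rose, and KLF4 and NR4A1 fell by 1.61 and 1.91. SOX2 rose and KLF4 fell among 10 stem cell genes. EGLN3 rose by 2.18 and ADM fell by 1.03 among 20 hypoxia genes, of which 0 rose and 1 fell adjusted over the list alone. Lists with a lone lower member were p53 targets (MDM2, by 1.57, of 15), the osteoblast lineage (OMD, by 4.53, of 10), the interferon response (OAS2, by 2.43, of 22), the stress response (HSPB1, by 1.70, of 22) and antigen presentation (B2M, by 1.14, of 17). Adjusted over the list alone, 0 genes passed among p53 targets, the interferon response and the stress response. In the same count 3 fell in the osteoblast list and 1 in antigen presentation. CYC1 rose by 1.05 among 42 genes of oxidative phosphorylation and HK2 by 0.74 among 22 of glycolysis. In both of these lists 0 genes passed adjusted over the list alone. In the lists for cholesterol synthesis, Hedgehog, cartilage, osteoclasts and macrophages, and endothelium 0 genes passed. Among members below the filter on dim probe sets, FMOD of the cartilage list (-2.39), PECAM1 of the endothelial list (0.84) and HERC5 of the interferon list (1.74) passed without it; they were chosen after their values were seen. The bone collagen COL1A2 differed by -0.93 and SPARC by -0.88, neither past the threshold, with tumorigenic means of 13.60 and 12.75.

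Lists with fewer than 5 measured genes were counted and not tested. FABP4 rose by 2.06 among 4 adipocyte markers, KRT7 by 0.81 among 3 epithelial markers and IL7R by 1.34 among 3 lymphocyte markers. ACTA1 fell by 3.70 among 2 skeletal muscle markers, on a probe set whose name marks it as able to cross-hybridise. Among 4 Notch genes 0 passed. The 3 measured sex-linked genes differed by 1.28 (EIF1AX), 0.52 (DDX3X) and 0.32 (KDM6A), and 0 passed over all genes, while 2 passed adjusted over the list alone.

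In all, 2580 of 21462 tested probe sets passed, 1563 of them higher and 1017 lower in the tumorigenic lines. At the gene level 1109 of 9145 passed, 686 higher and 423 lower. The higher share of the calls, 60.6%, was 78.7% with the arrays centred on the hybridization controls. Higher calls were the minority without UWKOS6 (34.6%), without both UWKOS6 and UWKOS8 (33.3%), and with the GAPDH or the mean transcript-end ratio as a covariate (36.8% and 36%). Large differences leaned the other way: 146 probe sets were at least 4-fold higher and 245 at least 4-fold lower. The groups did not overlap for 38.2% of the tested probe sets. Without ties, the average share over the 10 ways to split the lines into 3 and 3 is 10% for any data. Probe sets vary together across the lines, so 1 split can lie far above 10%, and chance was not measured by this share. These counts rested on few lines: leaving out 1 line at a time left 52 probe sets past the threshold without UWKOS6, 437 without UWKOS8, 647 without UWKOS3, 1141 without UWKOS1, 1343 without UWKOS2 and 3169 without UWKOS7. With the GAPDH transcript-end ratio as a covariate 19 probe sets and 9 genes passed, and without both UWKOS6 and UWKOS8 9 probe sets and 1 gene, FZD6, passed.

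The lines of each group resembled one another more than those of the other group. Pearson correlations across the tested probe sets ranged from 0.940 to 0.963 between non-tumorigenic lines, from 0.901 to 0.915 between tumorigenic lines and from 0.815 to 0.895 across the groups; they are across probe sets, which are not independent replicates. The first principal component held 55.6% of the variance and placed the groups on opposite sides.

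Control probe sets at both ends of GAPDH and ACTB gave transcript-end ratios, a sign of RNA quality, that were higher in part of the non-tumorigenic lines. For the ACTB pair with the widest spread the log2 ratio was 2.86 in UWKOS6 and 2.07 in UWKOS8, 0.82 in UWKOS2, and between 0.64 and 1.11 in the tumorigenic lines. The group difference over the 4 pairs was 0.27 to 1.06, non-tumorigenic minus tumorigenic, with two-sided exact permutation p between 0.2 and 0.4. Adjusted over the 6 control measures tested, p lay between 0.24 and 0.4; with 3 lines against 3 the exact p cannot go below 0.1.

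**Figure D3:**
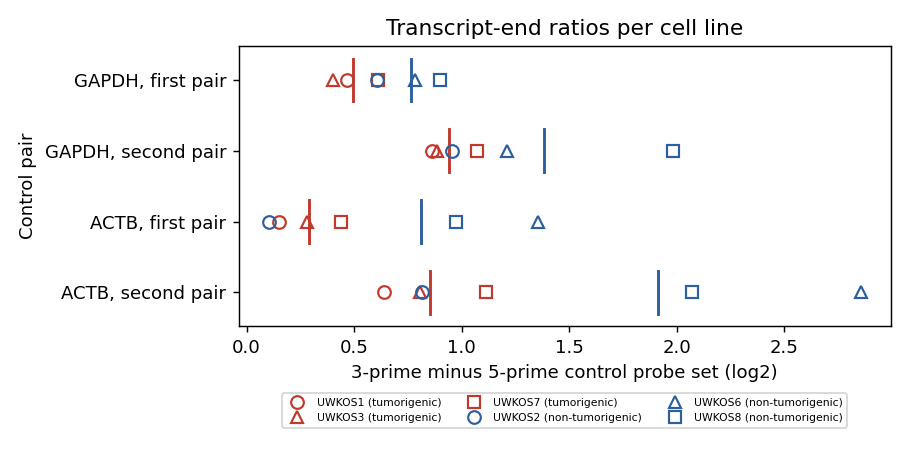
Difference between the 3-prime and the 5-prime control probe set (log2) in each of the 6 lines (points, 1 per line) with group means (vertical bars) for 4 control pairs. UWKOS6 and UWKOS8 lie highest in every pair; in the ACTB pair with the widest spread they reach 2.86 and 2.07.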

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

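In this part the bounds of the test on transcript-end ratios were fixed before its result was seen and its repeats with lines left out were added afterwards; the other tests were chosen after the result they bear on was seen. The poly-A control probe sets, spiked transcripts that no comparison of the report used, differed between the groups. Their 3-prime probe sets averaged 5.44 ± 0.12 (SD, n = 3) in the non-tumorigenic and 4.92 ± 0.09 (SD, n = 3) in the tumorigenic lines, a difference of 0.52 (two-sided exact permutation p = 0.1, the smallest that 3 lines against 3 allow). Adjusted over the 6 control measures, p was 0.24. The 12 such probe sets measure 4 spiked transcripts and are not independent; 11 were higher in the non-tumorigenic mean. Of the 12, 11 had a mean under 6.07, the value of the filter on dim probe sets, and whether they lay above background is unknown. The hybridization controls were 0.20 higher in the same lines (exact permutation p = 0.1).

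The difference between the groups was weighed against 2 other explanations, RNA integrity and the cell content of the lines. Tumorigenicity, the biological one that the design names, stays open and untested. Lower RNA integrity in part of the lines may contribute: with the mean transcript-end ratio as a covariate, the 2580 called probe sets kept their sign and their median size went from 1.28 to 1.14, 88.8% of its size, above the bound of 80% set against this explanation; 25 probe sets then passed, as the median SE went from 0.24 to 0.30 with fewer residual degrees of freedom. Without UWKOS6 and UWKOS8, the lines of the highest ratios, the 2580 also kept their sign, at a median size of 1.16 or 90.6%. Neither value can decide against RNA integrity, since the 2580 were called on the same arrays. Passing there favoured probe sets in which UWKOS2 lay near UWKOS6 and UWKOS8, so the kept signs and sizes partly followed from the selection. Both values also rest on UWKOS2, the lone non-tumorigenic line with ratios near the tumorigenic ones. Without UWKOS2 the covariate left 49.0%, where high ratios and the non-tumorigenic group coincide, against 88.9% to 93.5% without any other line. RNA integrity stays open as an explanation. The labels used here name no labelling or hybridization batch and no sex of the donor dogs, and neither was tested as a cause of the difference. More cells of a fibroblast type in the non-tumorigenic lines could lower the fibroblast list, whose median was -1.24 with 16 of 17 measured genes lower. Of the 17, 0 passed on their own. This explanation stays open, since the list cannot tell fibroblasts from tumour cells. The tumorigenic lines express its markers too, among them FN1 at a mean of 11.39.

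There are 10 ways to split the 6 lines into 3 and 3, too few for a share under 0.05. The real split gave 2580 probe sets and 1109 genes, 1 of the 10 splits with as many in each case, and the highest of the other splits gave 0 by limma; at an unadjusted p under 0.05 the real split gave 6844 probe sets and the other splits at most 1246. For the gene lists, 6 of the 10 splits, the real one included, gave at least the 9 lists that passed, and the highest of the others gave 11.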

How the results depend on the processing

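The alternatives added after seeing the data were centring on the hybridization controls, the mean transcript-end ratio as a covariate, leaving out both UWKOS6 and UWKOS8, and leaving out each line for the control ratios. Counts stayed within 1.5 times of 2580 probe sets and 1109 genes under both filters, quantile normalization and the 75th percentile. The same held for the intensity trend, robust eBayes and the mean of a gene's probe sets, where each applied. In the alternatives that refitted the probe sets, 0 called probe sets changed sign. They had been called on the same arrays, so the kept signs partly followed from the selection. Array weights gave 3895 probe sets. The GAPDH covariate gave 19 probe sets and 9 genes, the mean-ratio covariate 25 and 11, and leaving out both UWKOS6 and UWKOS8 9 and 1; these fits have fewer residual degrees of freedom. Leaving out 1 line gave 52 to 3169 probe sets and 12 to 1313 genes, lowest without UWKOS6. Gene lists past the test numbered 0 with an estimated correlation and 5 with fry, of which 4 were among the 9 that passed and the fifth was the osteosarcoma list, and 8 to 13 elsewhere. Lists past camera only under alternatives were the osteoblast list in 7, interferon in 5, cholesterol synthesis in 3, hypoxia and oxidative phosphorylation in 2 each, and cartilage, antigen presentation and immediate early genes in 1 each. Centring on the hybridization controls moved the median of all probe sets from 0.03 to 0.23 and the higher share of calls from 60.6% to 78.7%. The control ratio difference stayed between 0.41 and 0.87 when 1 line was left out. Sign changes among named genes concerned genes that had not passed: with the GAPDH covariate EZR 0.0874, MET -0.0692 and SETD2 0.00736; with the mean of a gene's probe sets EZR 0.25, VEGFA 0.0852 and SETD2 0.0517; on the hybridization controls ERBB2 0.0250 and SETD2 0.12; with the mean-ratio covariate EZR 0.0256; without UWKOS6 and UWKOS8 EZR 0.0699 and FOS 0.27; and, leaving out 1 line at a time, SETD2 from -0.29 to 0.16, ERBB2 from -0.55 to 0.12 and FOS from -1.23 to 0.53. The cause of these changes was not tested. The planned offsets did not apply to a log2 table and were not run. Signal over background is unknown here without detection calls, so a difference between a mean under 6.07 and a bright group has an uncertain size. No paired analysis was possible because the replicate numbers only follow accession order.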

Other observations

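All tests in this part were chosen after the result was seen. Some transcripts varied widely between lines of the same group. The cartilage matrix protein COMP was at 13.71 in UWKOS6 and 14.64 in UWKOS8, at 8.08 in UWKOS2 and between 6.25 and 6.75 in the tumorigenic lines, and did not pass (limma adjusted p = 0.0692). ACAN, the core protein of a cartilage proteoglycan, was at 9.56 in UWKOS8 and at most 5.99 in the other lines. CDKN1A, a cell cycle inhibitor induced by p53, was at 12.36 in UWKOS1, 13.29 in UWKOS6 and 13.12 in UWKOS8, and between 8.28 and 9.06 in the other lines. These genes were chosen after their values were seen.

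In UWKOS1 alone, a run of neighbouring genes was low. Of 8651 genes in chromosomal order, 20 lay more than 2 below every other line in UWKOS1, and 10 of them fell in a stretch from TMEM135 to TMEM126B with PRSS23, ME3, HIKESHI, EED, PICALM, CCDC89, CREBZF and TMEM126A. In that stretch UWKOS1 stayed at or below 4.95 for those genes, and TMEM126A was at 2.35 against at least 11.41 elsewhere. These genes formed 8 neighbouring pairs, against 0.0433 on average in 10000 shuffled gene orders. Chance placement of low genes is argued against by this permutation test (p = 1e-04, the smallest the shuffles can give; 0.0014 adjusted over the 14 patterns scanned). A candidate explanation is loss of a chromosome segment in UWKOS1. Other probe sets in the stretch were counted only where their mean without UWKOS1 reached the value of the filter on dim probe sets. Of these 12, 11 (91.7%) were lower in UWKOS1 than in every other line. Choosing probe sets that are bright in the other lines favours a lower UWKOS1, so this share partly followed from the selection and does not decide for loss. The 12 also belong to the genes of the run apart from SYTL2, and a probe set of CREBZF was not lower. Silencing of the stretch without loss of DNA was not tested, and no DNA was measured.

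The low EIF2S3 probe set had values near 3 in all 3 tumorigenic lines and near 10.8 in the others. Loss of EIF2S3 expression is argued against by its other probe sets, which averaged 0.55 higher in the tumorigenic lines, with every tumorigenic value above every non-tumorigenic one. Sex chromosomes that differ between the groups stay possible. The 3 measured X-linked genes of the fixed list were all higher on average in the tumorigenic lines, with a median difference of 0.52. Of them 0 passed over all genes and 2 passed adjusted over the list alone. Other X-linked genes were not examined as a set. The labels used here do not give the sex of the donor dogs, so whether it differs between the groups is unknown. A transcript variant or sequence difference under that probe set could give such a pattern too and was not tested.

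In UWKOS3 alone, RNLS, STAMBPL1 and the smooth muscle actin gene ACTA2, which are neighbours, were low, ACTA2 at 3.83 against at least 11.44 in the other lines (2 pairs, adjusted p = 0.0305 by shuffled gene orders). Genes past the threshold also lay next to each other more often than shuffled orders gave, with 69 neighbouring pairs against 48.4 among higher genes (adjusted p = 0.00793) and 33 against 18.2 among lower genes (adjusted p = 0.007). Shuffling treats neighbouring genes as independent, while some pairs were related genes, such as COL4A1 with COL4A2 and FABP5 with FABP4. The source of the excess was not tested.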
